A study of Homo sapiens with 15 samples.

How the data were processed

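Total RNA from MCF-7 cells, a human breast cancer line, was measured on 15 Affymetrix Human Genome arrays of the U133 series, version A 2.0, 3 for each of 5 groups, with a knockdown of Luciferase as the control and of PARP-1, PARG, SIRT1 or macroH2A. Per the labels, the 3 arrays of a group come from cell lines that were generated independently of each other. Groups and replicate numbers were taken from the sample titles.

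The deposited values are on a log2 scale. Per the labels' series design text, the authors obtained signals with the Affymetrix software GCOS, whose version is not given in the sources used here, scaled each array to a target of 500, adjusted the signals for batches of RNA isolation with an empirical Bayes method, set values under 0.01 to 0.01, took log2 and centred first each array and then each probe set on its median. These steps shape what can be measured. The centring removes the level of each probe set, so that weakly and strongly expressed genes look alike, and detection calls were not used here. The floor makes some values very low, down to −16.8, and between 55 and 176 probe sets per array lay below −4. The batch adjustment removes variation before any test, and which arrays shared a day is not given in the sources used here. The table held 15 arrays with 0 missing values, the largest absolute array median was 0.0268 and the median of each probe set was 0. All 15 columns of values were used.

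Probe sets were named by the platform annotation. Of all probe sets, 62 were Affymetrix controls, 19064 had 1 gene symbol, 1043 had several and 2108 had none, and the last 2 kinds were left out of gene tests. The Entrez identifiers of 19052 of the 19064 probe sets were found in a RefSeq gene table of assembly GRCh38, used only for symbols, which changed 0 of them. A gene was the mean of its probe sets, which gave 11963 genes, 4310 of them with more than 1 probe set. Genomic positions are not given, because no genome build belongs to the deposited values.

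Tests used limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes without trend), with 1 mean per group fitted to all 15 arrays, which left 10 residual degrees of freedom. Two-sided p values were adjusted by the Benjamini-Hochberg method over all genes within each of the 10 comparisons, and a gene was called at an adjusted p under 0.05. A moderated F test compared the 5 groups. The targeted genes were also compared by an exact two-sided permutation test of 3 arrays against 3, whose smallest p is 0.1. In all 10 comparisons, each called gene had its 3 arrays of one group on one side of the 3 of the other. Over all genes this held for 15.5% to 18.9%, where chance gives 10%.

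Gene lists, 32 in all, were written from textbook knowledge before the data were examined, as were the tests of the comparisons, the rule for naming genes and the alternatives, except for those named as chosen later where they are reported. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 32 lists of a comparison. No list called this way was called with a correlation estimated from the arrays, and the adjusted p of that test stands beside each call. Other splits of the 6 arrays compared also called lists, up to 5 for PARP-1, 8 for PARG, 5 for SIRT1 and 4 for macroH2A. Chance is therefore not excluded for the lists called. Members were counted as higher or lower over all genes tested and again adjusted over the list alone. A gene was named when it was a target, when it was among the 10 largest rises or falls of a knockdown (5 between knockdowns) that passed, with arrays that did not overlap and no opposing probe set, when it was among the 4 leading members of a called list (2 of a list described without a call), or when it was called in all 4 knockdowns. Members of fixed lists that passed over all genes, and genes called in 3 knockdowns, were named after their values had been seen.

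Similarity of the knockdowns was measured by correlation and covariance of log2 changes across genes, beside 100 simulations of unchanged groups that share a simulated control. The tests were checked on simulated data made from the real genes' spread. In a simulated PARP-1 comparison of 11963 genes, 25%, 50% and 71% of 200 genes changed 1.5-fold, 2-fold and 4-fold were called, with 4, 7 and 6 false calls. Lists shifted by 0.5 (log2) were called in 20 of 20 runs, and 1 of 620 unchanged lists was. These simulations shuffle each gene on its own and hold no variation shared between genes, so they do not measure how often camera calls an unchanged list on real arrays, and shifts as small as the reported medians were not simulated. The 15 arrays limit the precision, and differences under 2-fold were mostly below it.

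Alternatives were each probe set on its own, the probe set with the smallest spread per gene, quantile normalization, leaving out the noisiest 25% of genes or genes with a value below −4, array weights, robust moderation, other thresholds, a fit to only the 6 arrays compared, the replicate number as a block, and leaving out in turn each array of the groups compared. Where 1 array of a group was left out, the pooled spread of all groups was used. Other splits of the samples, at most 100 per result, were drawn with a fixed seed, once freely and once with 1 array of each replicate number in each group.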

Results

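Gene expression was compared between knockdown lines and control lines of MCF-7, a human breast cancer cell line that depends on estrogen. The control was a knockdown of Luciferase, a firefly enzyme that human cells lack. The targets were PARP-1, the main enzyme that makes poly(ADP-ribose) from NAD, PARG, the enzyme that degrades poly(ADP-ribose), SIRT1, a deacetylase that uses NAD, and macroH2A, a histone variant whose macro domain can bind ADP-ribose. Each of the 5 groups held 3 arrays from 3 independently generated cell lines. So n = 3 throughout, and the spread between replicates is one between lines. The 15 arrays gave values for 11963 genes. The values were log2 signals centred on each probe set's median over the 15 arrays, so they show differences between samples and not the level of a gene. The values had been adjusted for batches of RNA isolation before deposit, which can make the spread within groups look too small and the counts of called genes too high. Fitted without the replicate number, 43, 33, 38 and 73 genes were called for PARP-1, PARG, SIRT1 and macroH2A against Luciferase. With that number as a block, 6, 3, 8 and 3 were called. The number of arrays limits the precision, and a fold change near the floor of the signal is not a measure of how far expression moved. The array of Luciferase replicate 3 had a wider spread over genes than the rest, with an interquartile range of 0.443 against 0.269 to 0.320 on the other 14 arrays, and an ACTB 3′ minus 5′ signal of 0.350 (log2) against −0.144 to 0.133, a measure of RNA quality.

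The targeted transcripts were examined first. PARP1 was 6.55-fold lower in the PARP-1 knockdown lines (log2 change −2.71, SE 0.20, limma adjusted p = 3.6e-04), which left 15.3% of the Luciferase value. Its log2 changes in the PARG, SIRT1 and macroH2A lines were 0.03, 0.05 and 0.03. SIRT1 was 3.94-fold lower in its knockdown (−1.98, SE 0.12, adjusted p = 3.8e-05), at 25.4% of the Luciferase value. MACROH2A1 was lower in the macroH2A lines on both probe sets that stayed clear of the floor, by −3.24 (SE 0.211) and −3.14 (SE 0.222) on the log2 scale, each with an adjusted p of 1.3e-04 when probe sets were tested singly. The remaining MACROH2A1 probe set reached −13.8 and −13.9 on macroH2A arrays 2 and 3, and −3.28 on macroH2A array 1. The mean over the 3 probe sets (−5.65, SE 0.83, adjusted p = 0.0203) therefore rests partly on values near the floor. That gene-level call held with macroH2A replicate 1 left out and was lost without any other of the 6 arrays. The adjusted p was 0.0563 without macroH2A replicate 2, 0.0719 without replicate 3, and 0.0611, 0.0563 and 0.0595 without Luciferase replicates 1, 2 and 3. MACROH2A2, the second macroH2A gene, had a log2 change of 0.05 in the macroH2A lines (adjusted p = 0.930). PARG, measured by 1 probe set, had a log2 change of −1.51 in its own knockdown (SE 0.32, 35.0% of the Luciferase value) that did not pass the threshold (adjusted p = 0.0798, unadjusted p = 6.1e-04). Its Luciferase arrays ranged widely, with an SD of 0.515, and its log2 changes in the PARP-1, SIRT1 and macroH2A lines were −0.60, −0.33 and −0.45, none of which passed. In each knockdown, all 3 arrays lay below all 3 Luciferase arrays for the targeted gene, which gives an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow.

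**Figure D1:**
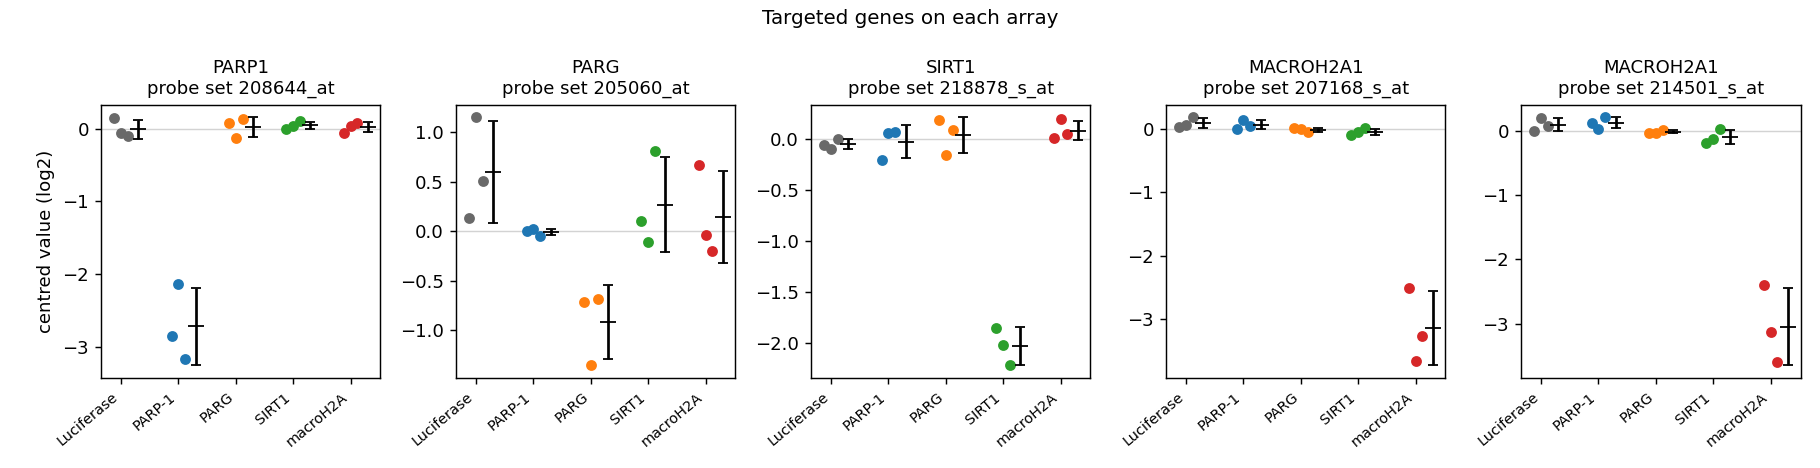
Centred log2 value (vertical axis) of the probe sets of the 4 targeted genes on each of the 15 arrays by group (horizontal axis), each point an array and each black bar the mean ± SD of 3 arrays. The knockdown arrays lie below the Luciferase arrays of the same panel, by −2.71 for PARP1, −1.51 for PARG, −1.98 for SIRT1 and −3.24 and −3.14 for the plotted MACROH2A1 probe sets. The MACROH2A1 probe set that reached the floor is not drawn.

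The comparison of the PARP-1 knockdown with Luciferase asked which transcripts differ between these lines. LTB, named below, was called in 3 knockdowns, IL1RL2 also in the macroH2A, TRIM17 in the PARG and ST3GAL5 in the SIRT1 lines. C1R, SH3BGRL, CALML5 and TMOD3 were called in all 4 knockdowns. Among the 4 knockdowns a limma F test gave C1R, SH3BGRL and TMOD3 an unadjusted p of 0.992, 0.745 and 0.119. A difference of the Luciferase lines would give the same values for these genes. Among the largest rises were C1R, a protease of the complement system (log2 change 2.32, SE 0.40, 4.98-fold, adjusted p = 0.0436), IL1RL2, the receptor for interleukin-36 (2.29, SE 0.35, 4.90-fold, adjusted p = 0.0229), and SH3BGRL (1.77, SE 0.24, 3.40-fold, adjusted p = 0.0191). LTB, a cytokine of the tumour necrosis factor family, rose by 1.52, ALDH1A3, an enzyme that makes retinoic acid, by 1.41, and CEACAM6, a cell surface adhesion protein, by 1.32. VASH2, FOXD3, CALML5 and TMOD3 completed the 10 largest rises, with changes between 0.91 and 1.07. After PARP1, the largest falls were in TXK, a tyrosine kinase of T cells (−2.64, SE 0.36, adjusted p = 0.0191), ADGRL3, an adhesion receptor (−2.41, SE 0.30, adjusted p = 0.0104), and TCAP, a protein of the sarcomere (−1.58, SE 0.29, adjusted p = 0.0473). They were followed by TRIM17 (−1.50) and the transcription factor gene PAX2 (−1.18). PFDN1, a subunit of the chaperone prefoldin, DUSP2, a phosphatase of MAP kinases, NVL and ST3GAL5 fell by −1.03, −0.75, −0.74 and −0.67. In all, 43 of 11963 genes passed an adjusted p of 0.05, 26 higher and 17 lower, and 1517 had an unadjusted p under 0.05. The count was 10 without Luciferase replicate 3, and 7, 11 and 11 without PARP-1 replicates 1, 2 and 3, with 5 higher and 6 lower without replicate 2. Of the 20 named genes, CALML5, TMOD3 and PARP1 passed whichever single array was left out, and the other 17 were lost without at least 1 array.

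Genes of cytosolic ribosomal proteins fell together in the PARP-1 lines, with 34 of 36 measured members below Luciferase and a median change of −0.14 (camera adjusted p = 2.3e-08, and adjusted p = 0.787 with an estimated correlation). No single member passed over all genes or adjusted over the list alone, and the members with the clearest change were RPL38 at −0.30 (SE 0.08), RPL12 at −0.20 (SE 0.07), RPL34 at −0.25 (SE 0.09) and RPL27 at −0.16 (SE 0.06). This list stayed past the threshold without Luciferase replicate 3 (median −0.12, adjusted p = 3.6e-05). Genes of DNA replication rose as a list, with 23 of 33 above Luciferase and a median of 0.13 (adjusted p = 0.0134, and adjusted p = 0.939 with an estimated correlation), among them CCNE1, the cyclin of the entry into S phase (0.29, SE 0.08), MCM5 (0.37, SE 0.10), PCNA (0.26, SE 0.08) and E2F1 (0.27, SE 0.10). M phase genes were above Luciferase in 27 of 34 cases (median 0.11, adjusted p = 0.0298, and adjusted p = 0.939 with an estimated correlation), with CDC20 at 0.35, CCNA2 at 0.40, CCNB2 at 0.28 and BIRC5 at 0.25. Interferon stimulated genes rose as a list, with 28 of 40 above Luciferase and a median of 0.21 (adjusted p = 0.0344, and adjusted p = 0.280 with an estimated correlation). Of these 40 genes 3 rose when adjusted over the list alone and 0 over all genes, and the leading members were the GTPase gene GBP1 (1.58, SE 0.30, adjusted p = 0.0568), PARP12 (0.77, SE 0.20), IFITM1 (0.38, SE 0.10) and TAP1 (0.55, SE 0.16). GBP1 had a value near the floor on 1 or more of the arrays, and its Luciferase arrays had an SD of 0.70. Ribosome biogenesis genes were above Luciferase in 15 of 19 cases (median 0.11, adjusted p = 0.0424, and adjusted p = 0.790 with an estimated correlation), including DDX21 at 0.24, BYSL at 0.34, NOLC1 at 0.24 and WDR12 at 0.14, and their adjusted p was 0.0955 after quantile normalization. In the replication, M phase and ribosome biogenesis lists 0 members passed over all genes and 0 adjusted over the list alone. Without Luciferase replicate 3 the calls of these last 4 lists ended, at medians of 0.06 for replication (adjusted p = 0.0925), 0.08 for M phase (0.127), 0.24 for interferon (0.0925) and 0.09 for ribosome biogenesis (0.348). Calls also ended for M phase without Luciferase replicate 2 (median 0.09, adjusted p = 0.192) or PARP-1 replicate 2 (0.03, 0.665), and for interferon without Luciferase replicate 2 (0.18, 0.0821) or PARP-1 replicate 1 (0.19, 0.102). That of ribosome biogenesis ended without PARP-1 replicate 1 (0.14, 0.0563) or 3 (0.08, 0.254). The ACTB 3′ minus 5′ value was 0.0350 ± 0.0869 (SD) in the PARP-1 arrays and 0.151 ± 0.172 in the Luciferase arrays, with an exact permutation p of 0.4, and GAPDH gave 0.0307 and 0.0431 (exact p = 0.5). With the ACTB value as a covariate the calls of the interferon list (median 0.22, adjusted p = 0.0783) and the ribosome biogenesis list (median 0.08, adjusted p = 0.312) ended. Those of M phase (0.15, adjusted p = 7.0e-04) and DNA replication (0.10, adjusted p = 0.0116) held, and the list of proteasome subunits came to be called (0.08, adjusted p = 0.0116). Outside these lists, QPRT, an enzyme of NAD synthesis, rose by 0.85 (adjusted p = 0.0229, 1 of 15 genes of NAD metabolism over all genes and 1 adjusted over the list alone), and ID3, an inhibitor of transcription factors downstream of BMP signals, fell by −0.66 (adjusted p = 0.0449). ID3 was the 1 gene of 27 of the TGF-beta and BMP pathway that passed over all genes, where 3 fell and 2 rose adjusted over the list alone.

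The PARG knockdown was compared with Luciferase to find transcripts that differ between these lines. C1R, SH3BGRL, TMOD3 and ATXN10, named below, were called in all 4 knockdowns and so do not single out PARG. Nor do MTR and NELL2, called in 3 knockdowns. QPRT and TRIM17 were also called in the PARP-1 lines and BHLHE40 in the macroH2A lines. C1R (2.28, SE 0.40, 4.86-fold, adjusted p = 0.0468), ELOA2, an elongin A paralog (1.63, SE 0.27, 3.10-fold, adjusted p = 0.0391), SH3BGRL (1.62, SE 0.24, 3.08-fold, adjusted p = 0.0299) and the amino acid transporter gene SLC6A14 (1.36, SE 0.17, 2.57-fold, adjusted p = 0.0140) rose the most. TMOD3 rose by 1.12 and ATXN10 by 1.05, followed by GNE, the first enzyme of sialic acid synthesis (0.87), QPRT (0.86), the methionine synthase gene MTR (0.82) and EFEMP1, an extracellular matrix protein (0.75). The largest falls were in TRIM17 (−1.79, SE 0.21, adjusted p = 0.00743), ANO2, a calcium-activated chloride channel (−1.55, SE 0.24, adjusted p = 0.0309), BTN3A1, a butyrophilin (−1.54, SE 0.26, adjusted p = 0.0408). Next came CLC (−1.20, SE 0.21, adjusted p = 0.0459) and NELL2, a secreted protein with EGF-like repeats (−1.14, SE 0.12, adjusted p = 0.00449). The kinase gene NEK7 (−0.92), BHLHE40, a transcription factor induced by hypoxia (−0.83, adjusted p = 0.0408), BAZ2A, a subunit of a complex that silences ribosomal DNA (−0.79), AMPH (−0.78) and WSB2 (−0.66) also fell. In total 33 genes passed, 21 higher and 12 lower, and 1587 had an unadjusted p under 0.05. The excess of rises turned to an excess of falls without PARG replicate 1 (5 higher and 10 lower) or replicate 3 (5 and 13). After quantile normalization the count was 21, with 16 higher and 5 lower. It was 17, 15 and 10 without Luciferase replicates 1, 2 and 3 and 15, 21 and 18 without PARG replicates 1, 2 and 3. SLC6A14, TMOD3, ATXN10, TRIM17 and NELL2 passed whichever array was left out, and the other 15 named genes were lost without at least 1 array.

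Genes of cholesterol and fatty acid synthesis rose together in the PARG lines, with 23 of 27 above Luciferase and a median of 0.15 (camera adjusted p = 0.00387, and adjusted p = 0.772 with an estimated correlation). INSIG1, a sterol sensor (0.49, SE 0.14), ACSL1 (0.33, SE 0.12), the lanosterol synthase gene LSS (0.52, SE 0.20) and TMEM97 (0.22, SE 0.09) led this list. Ribosome biogenesis genes rose as a list as in the PARP-1 lines, with 15 of 19 above Luciferase (median 0.11, adjusted p = 0.0216, and adjusted p = 0.637 with an estimated correlation), led by RRP9 at 0.55, NOLC1 at 0.28, NIP7 at 0.26 and DDX21 at 0.20. Cytosolic ribosomal protein genes fell as a list, with 29 of 36 below Luciferase (median −0.07, adjusted p = 0.0216, and adjusted p = 0.830 with an estimated correlation), among them RPL38 at −0.24, RPS21 at −0.21, RPL18 at −0.37 and RPS15A at −0.13. Oxidative phosphorylation genes fell as a list, with 33 of 40 below Luciferase (median −0.07, adjusted p = 0.0216, and adjusted p = 0.830 with an estimated correlation). Its leading members were the ATP synthase subunit genes ATP5F1B and ATP5F1C, both at −0.15 (SE 0.07), and the complex I subunit genes NDUFB8 at −0.17 (SE 0.09) and NDUFA2 at −2.15 (SE 1.20). The SE of NDUFA2 was far above the list's median of 0.079, so the size of its change is not well measured. In each of these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. Without Luciferase replicate 3 the cholesterol list stayed past the threshold at a lower median (0.11, adjusted p = 0.0490), while the calls of ribosome biogenesis (median 0.08, adjusted p = 0.202), ribosomal proteins (−0.04, 0.228) and oxidative phosphorylation (−0.04, 0.366) ended. All 4 calls ended without PARG replicate 3, at medians of 0.13, 0.10 and −0.08 and an adjusted p of 0.0651 for the cholesterol, ribosome biogenesis and oxidative phosphorylation lists, and −0.06 (0.0862) for ribosomal proteins. The last also ended without PARG replicate 1 (−0.07, 0.0516), and that of oxidative phosphorylation without PARG replicate 2 (−0.05, 0.226) and with the probe set of smallest SD for each gene. The PARG arrays had an ACTB 3′ minus 5′ value of −0.0574 ± 0.0839 (SD) against 0.151 ± 0.172 in Luciferase, lower on all arrays, with an exact permutation p of 0.1, the smallest possible. The GAPDH value was −0.00576 against 0.0431 (exact permutation p = 0.1). QPRT was the gene of NAD metabolism that passed over all genes in the PARG lines (adjusted p = 0.0299), and 3 of the 15 rose when adjusted over the list alone. BHLHE40 was the 1 of 38 genes of glycolysis and hypoxia that fell, by either count.

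The next comparison asked which transcripts differ from Luciferase in the knockdown lines of SIRT1, a deacetylase that acts on histones and transcription factors. C1R, SH3BGRL, TMOD3, ATXN10 and CALML5, named below, were called in all 4 knockdowns and so do not single out SIRT1. Nor do LTB, UGT8, MTR, MSMB and NELL2, called in 3 knockdowns. ZNF814, NAT1 and RAB31 were also called in the macroH2A lines and ST3GAL5 in the PARP-1 lines. C1R (2.37, SE 0.40, 5.18-fold, adjusted p = 0.0364), ARHGAP4, a GTPase activating protein for Rho (1.92, SE 0.32, 3.79-fold, adjusted p = 0.0327), SH3BGRL (1.56, SE 0.24, 2.94-fold, adjusted p = 0.0279) and LTB (1.43, SE 0.25, 2.70-fold, adjusted p = 0.0441) showed the largest rises. TMOD3 rose by 1.10, ATXN10 by 0.99, CALML5 by 0.87, UGT8, the enzyme that makes galactosylceramide, by 0.82, MTR by 0.80 and MSMB by 0.71. CADPS, a protein that primes dense-core vesicles for release, had the largest fall (−2.91, SE 0.50, 7.49-fold lower, adjusted p = 0.0420), ahead of SIRT1 itself, ZNF814 (−1.80, SE 0.21, adjusted p = 0.00421), the tight junction gene CLDN14 (−1.64, SE 0.25, adjusted p = 0.0251) and CDC42EP3, an effector of CDC42 (−1.29, SE 0.20, adjusted p = 0.0251). NELL2 fell by −1.19, ST3GAL5, the enzyme that makes the ganglioside GM3, by −1.01, NAT1, an arylamine acetyltransferase, by −0.90, and DEGS1, the enzyme that turns dihydroceramide into ceramide, by −0.85. With 18 genes higher and 20 lower, 38 genes passed in the SIRT1 lines, and 1460 had an unadjusted p under 0.05. The count was 17 and 16 without Luciferase replicates 1 and 3, with 10 higher and 7 lower and 10 higher and 6 lower, and 16, 22 and 16 without SIRT1 replicates 1, 2 and 3. TMOD3, ATXN10, CALML5, SIRT1, ZNF814, NELL2, ST3GAL5, RAB31 and DEGS1 passed whichever array was left out, and the other 11 of the 20 named genes were lost without at least 1 array.

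Of 37 measured estrogen receptor target genes 3 fell in the SIRT1 lines, both over all genes and adjusted over the list alone. They were TFF1, a secreted trefoil peptide and standard marker of estrogen response (−0.81, SE 0.12, adjusted p = 0.0251), RAB31, a GTPase of vesicle transport (−0.93, SE 0.12, adjusted p = 0.0119), and the transcription factor gene MYBL1 (−0.39, SE 0.07, adjusted p = 0.0479). The list as a whole was not called (camera adjusted p = 0.166), with 22 members below and 15 above Luciferase. Among 24 p53 targets GADD45A fell (−0.61, adjusted p = 0.0492), 1 gene over all genes and 3 adjusted over the list alone. Among 38 genes of glycolysis and hypoxia the muscle phosphofructokinase gene PFKM fell (−0.41, adjusted p = 0.0492), 1 over all genes and 2 adjusted over the list alone. Basal and mesenchymal genes had 19 of 27 members below Luciferase, 0 of which passed over all genes and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.121). By camera 0 of the 32 lists were called for SIRT1, where 9 had an unadjusted p under 0.05, and fry called 1, the list of the knockdown targets. The test with an estimated correlation called 0. The camera count was 5 without Luciferase replicate 1 and 3 without Luciferase replicate 3. On the SIRT1 arrays the ACTB 3′ minus 5′ value was −0.0285 ± 0.0429 (SD), lower than on all Luciferase arrays (exact permutation p = 0.1), while that of GAPDH was 0.0201 against 0.0431 (exact permutation p = 0.6).

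The macroH2A knockdown was compared with Luciferase to find transcripts that differ between these lines. C1R and SH3BGRL, named below, were called in all 4 knockdowns and so do not single out macroH2A. Nor do LTB and NELL2, called in 3 knockdowns. IL1RL2 was also called in the PARP-1 lines, and ZNF814 and NAT1 in the SIRT1 lines. C1R (2.26, SE 0.40, 4.79-fold, adjusted p = 0.0332), the protamine gene PRM2 (2.18, SE 0.41, 4.52-fold, adjusted p = 0.0447), IL1RL2 (2.00, SE 0.35, 4.01-fold, adjusted p = 0.0332), the metalloprotease gene ADAMTS6 (1.95, SE 0.38, 3.87-fold, adjusted p = 0.0469) and FAM215A (1.92, SE 0.28, 3.79-fold, adjusted p = 0.0203) rose the most. GBP1, a GTPase induced by interferon, rose by 1.65 with a value near the floor on 1 or more arrays, and SH3BGRL rose by 1.51, DCBLD2 by 1.46, LTB by 1.41 and ISL1, a LIM homeodomain transcription factor, by 1.35. After MACROH2A1 the largest falls were in the semaphorin gene SEMA6A (−2.05, SE 0.31, adjusted p = 0.0203), DPP6, an accessory subunit of potassium channels (−1.82, SE 0.34, adjusted p = 0.0447), NELL2 (−1.74, SE 0.12, adjusted p = 1.5e-04), the testis kinase gene TSSK2 (−1.68, SE 0.30, adjusted p = 0.0332) and ZNF814 (−1.29, SE 0.21, adjusted p = 0.0239). PVALB, a calcium binding protein, fell by −1.18, CAV2, a component of caveolae, by −1.11, NAT1 by −1.02 and the co-chaperone gene DNAJC12 by −1.01. In the macroH2A lines 73 genes passed, 47 higher and 26 lower, and 1592 had an unadjusted p under 0.05. The count was 12, 32 and 20 without Luciferase replicates 1, 2 and 3 and 14, 26 and 6 without macroH2A replicates 1, 2 and 3. The excess of rises turned to an excess of falls without macroH2A replicate 1 (4 higher and 10 lower) or replicate 2 (8 and 18). NELL2 and PVALB passed whichever array was left out, and the other 18 named genes were lost without at least 1 array.

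M phase genes rose as a list in the macroH2A lines, with 31 of 34 above Luciferase and a median of 0.17 (camera adjusted p = 0.00152, and adjusted p = 0.969 with an estimated correlation). CCNA2, a cyclin of S phase and mitosis (0.45, SE 0.12), the kinesin gene KIF20A (0.39, SE 0.11), CDC20, an activator of the anaphase promoting complex (0.32, SE 0.10), and BIRC5, known as survivin (0.32, SE 0.10), were its leading members, and 0 of the 34 passed over all genes or adjusted over the list alone. The call held without Luciferase replicate 3 (adjusted p = 0.0221) and ended without Luciferase replicate 2 (median 0.14, adjusted p = 0.0609) or macroH2A replicate 3 (0.11, 0.0591). The number of lists called was 5 without Luciferase replicate 3 and 3 without macroH2A replicate 1. In 8 of the other 31 lists, which were not called, single members passed over all genes, the knockdown targets included. Of 37 estrogen receptor targets TFF1 (−0.70, SE 0.12) and RAB31 (−0.70, SE 0.12) fell, both at an adjusted p of 0.0332, so that 2 fell over all genes and 3 adjusted over the list alone, while 1 rose adjusted over the list alone (camera adjusted p = 0.402). BHLHE40 fell by −0.87 (adjusted p = 0.0238), 1 of 38 genes of glycolysis and hypoxia over all genes and 2 adjusted over the list alone. LIG3, a DNA ligase of single strand break repair, rose by 0.54 (adjusted p = 0.0203), 1 of 18 genes of that pathway by either count, and UGDH, the enzyme that makes UDP-glucuronate, rose by 0.74 (adjusted p = 0.0239), 1 of 27 targets of NRF2 over all genes, where 2 rose and 2 fell adjusted over the list alone. The ACTB 3′ minus 5′ value of the macroH2A arrays was 0.0245 ± 0.0236 (SD), below all Luciferase arrays, with an exact permutation p of 0.1. That of GAPDH was −0.0142 against 0.0431 (exact permutation p = 0.1).

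Markers of cell types other than the tumour epithelium were tested as 2 lists. Of 18 fibroblast and stromal markers and 17 leukocyte markers, 0 rose or fell over all genes in any of the 4 comparisons. Adjusted over the list alone, 1 leukocyte marker rose in the macroH2A lines. The fry test for changes in either direction called the leukocyte list in the PARG lines (adjusted p = 0.0217), 1 of 21 lists that it called there. The camera adjusted p ranged from 0.593 in the PARP-1 lines to 0.983 in the PARG lines for the fibroblast list and from 0.564 in the SIRT1 lines to 0.983 in the PARG lines for the leukocyte list.

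**Figure D2:**
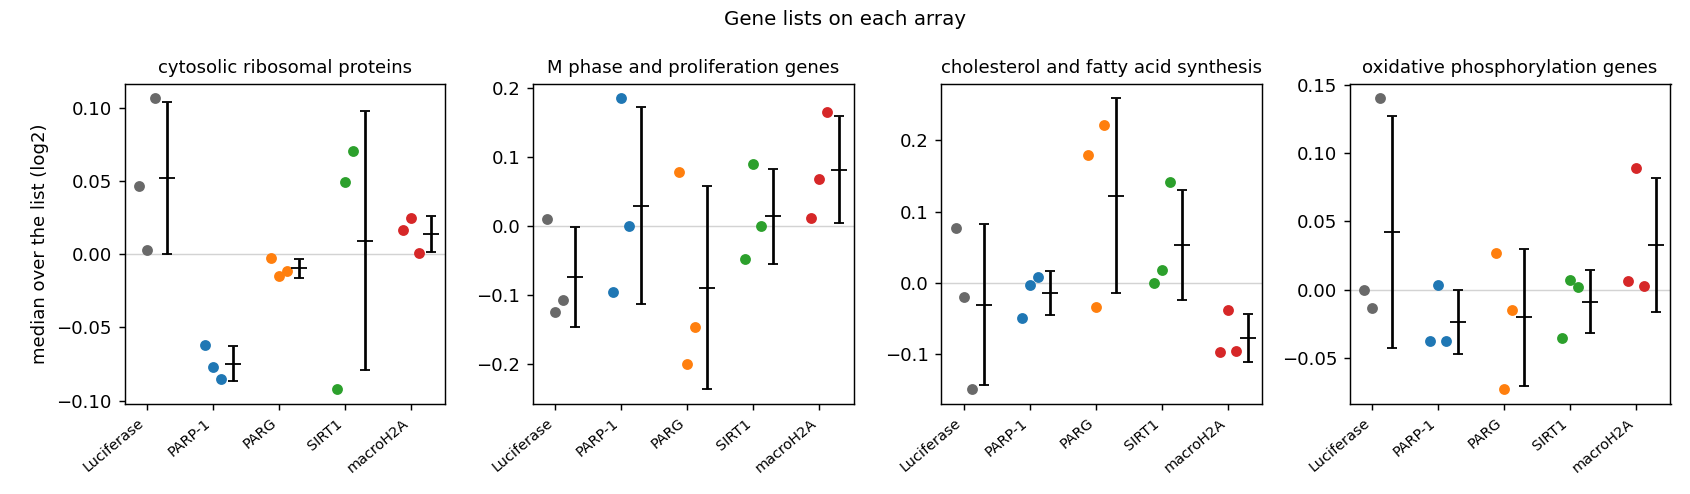
Median of the centred log2 values over the genes of 4 lists (vertical axis) on each array by group (horizontal axis), each point an array and each black bar the mean ± SD of 3 arrays. Ribosomal protein genes lie between −0.0854 and −0.0618 on the PARP-1 arrays, and the lowest array for them is SIRT1 replicate 1 at −0.0921. Luciferase replicate 3 is the highest array for ribosomal protein genes at 0.107, the highest array for oxidative phosphorylation at 0.140 and the lowest for cholesterol synthesis at −0.148.

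Knockdowns were then set against each other, which tests whether a transcript differs between the lines of 2 knockdowns. Whether it depends on the targeted proteins was not tested. Between PARP-1 and PARG, the enzymes that make and degrade poly(ADP-ribose), 15 genes differed, 8 higher and 7 lower in the PARP-1 lines. The sulfotransferase gene CHST2 was higher by 2.08 (SE 0.29, adjusted p = 0.0262), TOX3, a chromatin protein, by 1.24 (SE 0.15, adjusted p = 0.0107), SLC49A3 by 1.10, PADI2, an enzyme that turns arginine into citrulline, by 1.05 and WSB2 by 0.76. Beside PARP1 (−2.74), CD1E, a lipid antigen protein (−2.35, SE 0.34, adjusted p = 0.0321), FRMD1 (−1.22), the polarity gene PARD3 (−0.81) and SMPDL3A (−0.61) were lower. PARP-1 and SIRT1 lines, with knockdowns of enzymes that both consume NAD, differed in 12 genes, 7 higher and 5 lower in the PARP-1 lines. SIRT1 (2.00), ZNF814 (1.43), GBX2 (1.26), DUSP5 (0.88) and RAB31 (0.88) were higher, and PARP1 (−2.76), PAX2 (−1.53, SE 0.21, adjusted p = 0.0272), SSX3 (−1.50), PARD3 (−0.98, SE 0.13, adjusted p = 0.0235) and FAM117A (−0.67) lower. Against the macroH2A lines, the PARP-1 lines differed in 7 genes. MACROH2A1, TNFSF8, a ligand of the tumour necrosis factor family (2.33, SE 0.32, adjusted p = 0.0386), CEACAM6 (1.48) and NELL2 (1.20, SE 0.12, adjusted p = 0.00368) were higher and TXK (−3.04, SE 0.36, adjusted p = 0.0131), PARP1 (−2.74) and GUCY1A2 (−0.96) lower. The PARG and SIRT1 lines differed in 15 genes, 9 higher and 6 lower in the PARG lines. They were led by CD1E (2.24), SIRT1 (2.07), CLDN14 (1.61), PLCL2 (1.60) and ZNF814 (1.59) on the higher side and ANO2 (−1.59), PAX2 (−1.42), SLC49A3 (−1.32), WSB2 (−0.80) and PADI2 (−0.78) on the lower. CD1E (2.65, SE 0.34, adjusted p = 0.0228) and SLC6A14 (1.57, SE 0.17, adjusted p = 0.0176) were higher and LXN, a carboxypeptidase inhibitor (−0.95), and CLIC4 (−0.69) lower in the PARG than in the macroH2A lines. These were the 4 genes called there. Between SIRT1 and macroH2A 6 genes differed, with PARD3 higher in the SIRT1 lines (0.91) and SIRT1 (−2.11), SCNN1A, a subunit of the epithelial sodium channel (−1.44, SE 0.21, adjusted p = 0.0462), MCTP1 (−1.08), LXN (−1.07, SE 0.11, adjusted p = 0.00582) and DEGS1 (−0.72) lower. Whichever array was left out, PARP1 and SIRT1 kept their calls in 3 comparisons each, NELL2 between PARP-1 and macroH2A, and LXN between SIRT1 and macroH2A. The calls of the other named genes were lost without at least 1 array.

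Those counts were small, and they moved with single arrays. For PARP-1 against PARG the count was 1, 3 and 3 without PARP-1 replicates 1, 2 and 3 and 9 and 7 without PARG replicates 2 and 3. It was 3 and 4 without PARP-1 replicates 1 and 3 and 4 without macroH2A replicate 3 for PARP-1 against macroH2A. For PARP-1 against SIRT1 it was 3, 5 and 4 without PARP-1 replicates 1, 2 and 3 and 2, 2 and 7 without SIRT1 replicates 1, 2 and 3. The count for PARG against SIRT1 was 4 and 9 without PARG replicates 2 and 3 and 3, 3 and 7 without SIRT1 replicates 1, 2 and 3. It was 10 and 12 without PARG replicates 1 and 3 and 11, 10 and 0 without macroH2A replicates 1, 2 and 3 for PARG against macroH2A. Between SIRT1 and macroH2A it was 3 without SIRT1 replicate 1 or 3 and 11 and 3 without macroH2A replicates 1 and 3. The side with more genes also turned. It had more lower than higher genes without PARP-1 replicate 1, 2 or 3 for PARP-1 against PARG (0 and 1, 1 and 2, 0 and 3) and against SIRT1 (1 and 2, 2 and 3, 1 and 3), and without PARP-1 replicate 2 (1 and 7) or 3 (1 and 3) against macroH2A. The same held without PARG replicate 1, 2 or 3 for PARG against SIRT1 (2 and 8, 1 and 3, 2 and 7), while SIRT1 against macroH2A had 6 higher and 5 lower without macroH2A replicate 1. For PARG against macroH2A, with 2 higher and 2 lower, there were 1 and 9 or 2 and 10 without PARG replicate 1 or 3, and 9 and 2 or 8 and 2 without macroH2A replicate 1 or 2. At an unadjusted p under 0.05 the 6 comparisons gave between 1162 and 1308 genes.

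The last comparison asked whether the 4 knockdowns changed the same transcripts. Of 127 genes called in at least 1 knockdown, 88 were called in 1, 25 in 2, 7 in 3 and 7 in all 4, and 0 were called in opposite directions. The 7 genes called in all 4 were higher in each of them than in Luciferase. ATXN10 was 1.86-fold to 2.07-fold higher (0.89 to 1.05, SE 0.08, adjusted p at most 0.00142), and TMOD3, which caps actin filaments, was 1.88-fold to 2.17-fold higher (0.91 to 1.12, SE 0.10, adjusted p at most 0.00338). SH3BGRL rose by 1.51 to 1.77, LGALS3BP, a secreted galectin ligand, by 0.48 to 0.79, LYRM1 by 0.55 to 0.84, CALML5, a calmodulin-like protein of skin, by 0.49 to 0.92 and C1R by 2.26 to 2.37. For C1R the Luciferase arrays spread widely, with an SD of 0.892. HILPDA, PTPN3, MSMB, LTB, MTR and UGT8 were called higher in 3 knockdowns. They lay above Luciferase in the remaining 1 too, with changes of 0.41 for HILPDA in the SIRT1 lines (adjusted p = 0.0592), 0.60 for MTR in the PARP-1 lines (0.0804), and, in the PARG lines, 0.46 for PTPN3 (0.0650), 0.61 for MSMB (0.0733), 1.20 for LTB (0.0733) and 0.39 for UGT8 (0.230). NELL2 was called lower in 3, with changes of −1.14 in the PARG, −1.19 in the SIRT1 and −1.74 in the macroH2A lines, and its change of −0.54 in the PARP-1 lines did not pass (adjusted p = 0.0957). Among the 5 groups 91 genes differed by the moderated F test, and 30 without Luciferase replicate 3, a setting chosen after the data had been seen.

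**Figure D3:**
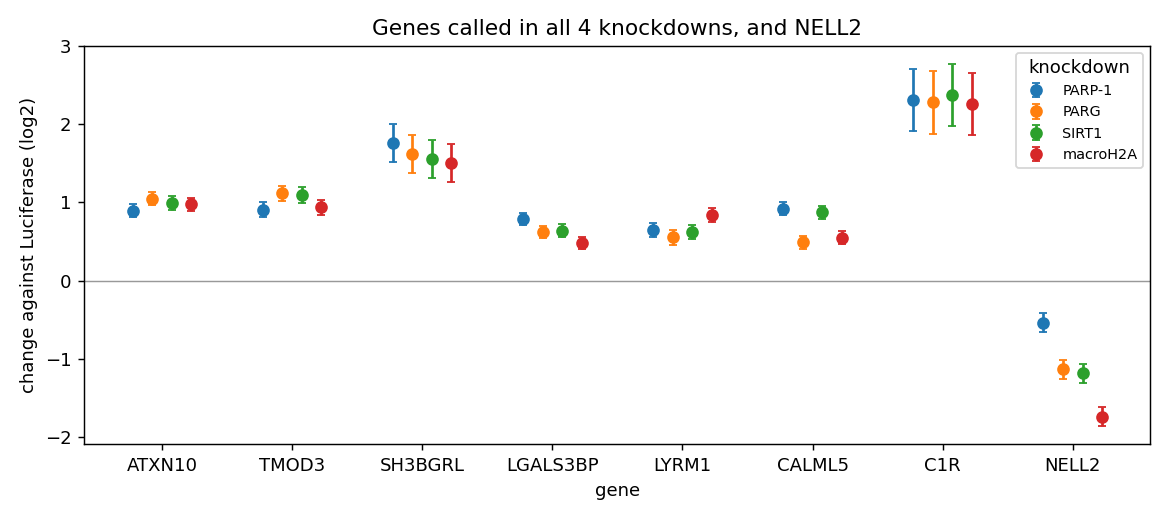
Log2 change against Luciferase (vertical axis) in each of the 4 knockdowns, with SE from the fit to all 15 arrays, for the 7 genes called in all 4 knockdowns and for NELL2 (horizontal axis). The 7 genes are higher in each knockdown, from 0.48 for LGALS3BP to 2.37 for C1R, and NELL2 is lower, at −1.74 in the macroH2A lines.

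Because the 4 knockdowns share the 3 Luciferase arrays, part of any likeness comes from those arrays. Across genes, which are not independent replicates, the log2 changes of 2 knockdowns had a Pearson correlation of 0.510 to 0.523 over the 6 pairs. Groups simulated without any effect, which shared a simulated control, gave 0.499 on average, with a range of 0.432 to 0.561. Spearman correlations were 0.489 to 0.510, against a simulated mean of 0.437, where the mean over the pairs ranged from 0.428 to 0.450. The simulations shuffled each gene on its own, so they hold no variation that genes share. The covariance was 0.238 to 0.250 against a simulated 0.185, a difference of 0.0535 to 0.0649. For 2 knockdowns, 8 to 16 genes were called higher in both and 1 to 8 lower in both, where independent lists would share 0.0316 to 0.102 and 0.0171 to 0.0435 genes. Simulated groups without effects shared 0.02 genes on average and at most 1. With 3 Luciferase arrays the control could not be split into 2 parts of at least 2 arrays each, so part of the excess may come from the shared controls.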

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

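Among the tests of this part, the single set of control lines, the replicate number, ribosomal protein genes without Luciferase replicate 3 or with genes that vary together, and the other 4 PARP-1 lists without Luciferase replicate 3 or with the ACTB value as a covariate were chosen after the result was seen.

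Several genes named for a knockdown differed from another knockdown in a direct limma test of the 2 groups, which compares their effects against the same Luciferase arrays. NELL2 was 1.20 (log2) higher in the PARP-1 than in the macroH2A lines, with changes against Luciferase of −0.54 and −1.74. CEACAM6 was 1.48 higher in the PARP-1 than in the macroH2A lines (1.32 and −0.16 against Luciferase) and TXK was −3.04 lower (−2.64 and 0.41). PAX2 was lower than in the SIRT1 lines both in the PARP-1 lines, by −1.53 (−1.18 and 0.35), and in the PARG lines, by −1.42 (−1.08 and 0.35). SLC6A14 was higher in the PARG lines than in the SIRT1 lines, by 1.18 (1.36 and 0.18), and than in the macroH2A lines, by 1.57 (1.36 and −0.21).

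ANO2 differed by −1.59 between the PARG and SIRT1 lines (−1.55 and 0.04 against Luciferase). WSB2 was 0.76 higher in the PARP-1 than in the PARG lines (0.10 and −0.66) and differed by −0.80 between the PARG and SIRT1 lines (−0.66 and 0.14). ZNF814, lower in the SIRT1 lines (−1.80), differed from them by 1.43 in the PARP-1 lines (−0.37) and by 1.59 in the PARG lines (−0.21). CLDN14 differed by 1.61 between the PARG and SIRT1 lines (−0.03 and −1.64), RAB31 by 0.88 between the PARP-1 and SIRT1 lines (−0.06 and −0.93), and DEGS1 by −0.72 between the SIRT1 and macroH2A lines (−0.85 and −0.13).

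Probe sets without a single gene, 3151 in all, belong to no comparison of the report. Of them 8 were called for the PARP-1 knockdown (5 higher and 3 lower), 11 for PARG (5 and 6), 6 for SIRT1 (6 and 0) and 12 for macroH2A (6 and 6), and 420, 409, 370 and 379 had an unadjusted p under 0.05. Groups of 3 arrays are too small for the check of single samples far from the others.

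The Luciferase arrays stood apart from the 4 knockdowns, with 79 genes called for Luciferase against the mean of the other groups. Without Luciferase replicate 3, which had the widest spread of values, the count was 22, equal to the highest count of a knockdown without 1 of its arrays (22, PARG without replicate 1), so this array stays open as an explanation. A difference of the single set of control lines cannot be told apart from an effect common to the 4 knockdowns, since the design holds no other control line, and 5 of the 7 genes called in all 4 knockdowns had an unadjusted p of 0.05 or more among the knockdowns. A shared response to the knockdowns is the biological explanation, and it remains untested.

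The replicate number took 2.77% of the variation within groups at the median gene, where simulated noise without batches gave 16.3%. An adjustment by replicate number before deposit may explain this, since the authors corrected for batches of RNA isolation, but which arrays shared a batch is not given in the sources used here. No biological explanation was tested.

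Ribosomal protein genes were lower in the PARP-1 lines at a median of −0.14. Luciferase replicate 3 alone is argued against as the whole cause, with a median of −0.117 without that array. With the ACTB 3′ minus 5′ value as a covariate the median was −0.124 (camera adjusted p = 3.7e-06). That value was highest on Luciferase replicate 3 (0.350), so this fit is not a separate argument, and a single control gene cannot decide on RNA quality in general. Variation that the genes of the list share between arrays of a group stays open, as does an effect of PARP-1, with an adjusted p of 0.787 under an estimated correlation. Without Luciferase replicate 3 the M phase, DNA replication, interferon and ribosome biogenesis lists had a lowest adjusted p of 0.0925 and medians of 0.08, 0.06, 0.24 and 0.09 (0.11, 0.13, 0.21 and 0.11 with all arrays), so the lost calls, 2 of which were also lost without Luciferase replicate 2, do not show whether this array is the cause. With the ACTB covariate the interferon list (median 0.21 before and 0.22 after, median SE of its genes 0.315 and 0.299, adjusted p = 0.0783) and the ribosome biogenesis list (0.11 and 0.08, SE 0.0987 and 0.104, adjusted p = 0.312) lost their calls, while M phase (median 0.15) and DNA replication (0.10) kept theirs, so RNA quality stays open for the 2 lost, and why the calls ended was not tested.

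The arrays were also split in other ways. For 2 groups of 3 arrays there are 10 splits, too few for a share under 0.05. Counts of genes against the highest other split were 43 and 2 for PARP-1, 33 and 1 for PARG, 38 and 2 for SIRT1 and 73 and 0 for macroH2A, and in each case 1 split, the real one, gave as many. It was also 1 split in the direct comparisons, with 15 and 0 for PARP-1 against PARG, 7 and 2 for PARP-1 against macroH2A, 12 and 0 for PARP-1 against SIRT1, 15 and 1 for PARG against SIRT1, 4 and 1 for PARG against macroH2A and 6 and 0 for SIRT1 against macroH2A. For lists the real count and the highest other were 5 and 5 for PARP-1, 4 and 8 for PARG, 0 and 5 for SIRT1 and 1 and 4 for macroH2A, with 2, 4, 10 and 8 splits of 10 that gave as many. Chance can therefore not be excluded for the lists called.

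Of 100 splits of the 15 arrays into 5 groups, drawn without regard to the replicate number, 1, the real one, gave as many as 91 genes by the F test, with 3 as the highest other. Splits that keep 1 array of each number in each group stand in the part on processing. The 79 genes of Luciferase against the rest were likewise reached by 1 split of 100, the real one, with 2 as the highest other. Other splits do not repeat the batch adjustment made before deposit, and the F test can count the targeted genes, so chance is not excluded for the rest. It cannot be excluded either for the mean correlation of the 4 knockdown effects, 0.518, which 39 of 100 splits reached, with 0.577 as the highest other.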

How the results depend on the processing

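The F test without Luciferase replicate 3, the splits with 1 array of each number per group and the simulated values without the noisiest 25% of genes were chosen after the result was seen. In this part, counts for several comparisons follow the order PARP-1, PARG, SIRT1 and macroH2A against Luciferase, then PARP-1 against PARG, PARP-1 against macroH2A, PARP-1 against SIRT1, PARG against SIRT1, PARG against macroH2A and SIRT1 against macroH2A. The reported counts are 43, 33, 38, 73, 15, 7, 12, 15, 4 and 6, with 91 genes in the F test among all groups. No named gene and no mean correlation reversed its direction, but the side with more called genes turned in several counts.

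PARP1 and SIRT1 kept their fall and passed the threshold without any 1 array, PARP1 at −3.00 to −2.49 (adjusted p from 1.9e-06 to 0.00474) and SIRT1 at −2.07 to −1.88. PARG stayed at −1.74 to −1.24 without passing (adjusted p from 0.0863 to 0.182). MACROH2A1 ranged from −7.03 to −4.94 without 1 array, with adjusted p values from 7.1e-12 to 0.0719. The probe set that reached the floor gave −10.6 (adjusted p = 0.0621) and did not pass, with knockdown values of −3.28, −13.8 and −13.9, while its other 2 probe sets passed. The cause was not tested.

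Without 1 array the counts ranged from 7 to 36, 10 to 21, 16 to 28, 6 to 32, 1 to 15, 3 to 8, 2 to 7, 3 to 10, 0 to 12 and 3 to 11, where the smaller number of arrays also lowers power. More genes rose than fell among the PARG calls (21 and 12) but not without PARG replicate 1 (5 and 10) or 3 (5 and 13), and among the macroH2A calls (47 and 26) but not without macroH2A replicate 1 (4 and 10) or 2 (8 and 18). The F test gave 30 genes without Luciferase replicate 3. The lone pair of arrays left in a group was assumed to vary like the other groups.

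With only the 6 arrays compared, limma called 1, 0, 0, 0, 0, 0, 0, 0, 0 and 1 genes, 0 of them among those reported. Fewer arrays were left there to estimate the spread, and the cause was not tested. With the probe set of smallest within-group SD per gene, which favours small spreads by construction, the counts that moved were 69, 74, 66, 112, 24, 30 and 22 for the first 7 comparisons, 38 for PARG against macroH2A, 13 for SIRT1 against macroH2A and 183 for the F test. Without the noisiest 25% of genes, where fewer genes were tested, they were 102, 107, 99, 119, 42, 37, 26, 50, 57 and 36, and 249 for the F test. An adjusted p under 0.10 gave 117, 110, 102, 127, 33, 40, 30, 40, 66 and 38, and 236 for the F test. An unadjusted p under 0.05 with at least a 1.5-fold change gave 630, 675, 674, 680, 560, 600, 576, 601, 621 and 563, and 938 for the F test. There, falls outnumbered rises for PARP-1 (303 higher and 327 lower), PARG (308 and 367), PARP-1 against macroH2A (279 and 321) and PARG against SIRT1 (254 and 347). For SIRT1, rises outnumbered falls with each probe set (32 and 27), the smallest SD (35 and 31), without the noisiest 25% (53 and 46) and at 0.10 (54 and 48). PARP-1 against PARG turned to falls with the smallest SD (11 and 13), without the noisiest 25% (18 and 24) and at 0.10 (16 and 17), PARG against SIRT1 to falls with the smallest SD (8 and 10), and SIRT1 against macroH2A to rises with each probe set (7 and 6).

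With each probe set on its own, counts moved for PARG (68), SIRT1 (59), PARG against SIRT1 (3), PARG against macroH2A (23) and SIRT1 against macroH2A (13). Quantile normalization moved those of PARG (21, of which 19 were among the 33), PARP-1 against SIRT1 (20), PARG against macroH2A (11, with 7 higher and 4 lower against 2 and 2) and SIRT1 against macroH2A (12, with 4 higher and 8 lower against 1 and 5). For PARG the split was 16 higher and 5 lower against 21 and 12. Array weights moved PARP-1 against macroH2A (19), PARP-1 against SIRT1 (22), PARG against macroH2A (13) and SIRT1 against macroH2A (12). Without genes that had a value below −4, SIRT1 against macroH2A gave 10. Other counts under these settings, and all 11 under robust moderation, stayed within 1.5 times the reported ones. Except where a reason is given, the cause was not tested.

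The mean correlation of the knockdown effects, 0.518, was 0.497 by Spearman and 0.564 without the noisiest 25%. Simulated unchanged groups gave 0.437 (0.428 to 0.450) and 0.499 (0.479 to 0.516). The simulations hold no variation that genes share, so a value above their range does not show a shared effect. Among the genes of the F test it was 0.575, which says nothing about similarity, since these genes were chosen for differing between groups and have no simulated value. It was 0.581 to 0.603 without 1 Luciferase array, where the shared control rests on fewer arrays.

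Lists called by camera, 5 for PARP-1, 4 for PARG, 0 for SIRT1 and 1 for macroH2A, were 0, 0, 0 and 0 with an estimated correlation and 2, 0, 1 and 0 by fry. Both PARP-1 calls of fry were the knockdown targets and the interferon list. The probe set of smallest SD gave 4 lists for PARG, 3 of them among those reported, without oxidative phosphorylation and with the TGF-beta and BMP pathway. For SIRT1 the probe set of smallest SD gave 8 lists and the genes without the noisiest 25% 1. Without 1 array the counts ranged from 1 to 7 for PARP-1, 0 to 4 for PARG, 0 to 5 for SIRT1 and 0 to 5 for macroH2A. The cause of these changes was not tested.

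Of 1927 values of named genes under alternatives, 1116 kept their side of the threshold and 808 no longer passed, 3 came to pass and 0 reversed. Those no longer past it were 566 of 1170 without 1 array, 86 of 172 for single probe sets, 22 of 195 with quantile normalization, 12 of 195 with array weights and 122 of 195 with the replicate number as a block.

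With the replicate number as a block, the counts were 6, 3, 8, 3, 1, 2, 2, 1, 0 and 2, and 5 in the F test, all of them among the genes reported, and MACROH2A1 had the same change of −5.65 with an adjusted p of 0.0965. Lists called with the block were 4 for PARP-1, 4 for PARG, 0 for SIRT1 and 1 for macroH2A, all among those reported, and the PARP-1 call lost was that of ribosome biogenesis (adjusted p = 0.0535). Some genes that had passed whichever array was left out did not pass with the block. They were SLC6A14 (limma adjusted p = 0.105) and TRIM17 (0.0640) in the PARG, RAB31 (0.0658) in the SIRT1 and PVALB (0.0638) in the macroH2A lines. TFF1 (0.0788) and MYBL1 (0.194), named for the SIRT1 lines as estrogen receptor targets beside RAB31, did not pass either. The block leaves 8 residual degrees of freedom against 10. The numbers were not taken as pairs, since the labels tie them to no shared batch and the check gave no pair above 0.1. The series design text does call the knockdown lines control-matched. Whether a knockdown line and a Luciferase line of the same number were made together is not clear from it. Arrays of the same number had a mean correlation of −0.0843 (−0.172 to −0.00228 over 30 pairs) and arrays of different numbers one of 0.0421. At the median gene the number took 2.77% of the within-group variation against 16.3% in simulated noise, so the number may be the batch already adjusted for. In that case the adjustment itself lowers the correlation of arrays of the same number, the check cannot show whether the numbers tie the arrays, 10 residual degrees of freedom are too many, the spread without the block may be underestimated, and the counts of 43, 33, 38, 73 and 91 may be too high. Luciferase against the mean of the other groups had 7 genes with the block and 79 without.

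In 100 splits that keep 1 array of each number in each group, 1, the real one, gave as many as the 91 genes of the F test (highest other 11) and 1 as many as the 79 genes of Luciferase (highest other 4). With the replicate block, 1 split reached the 5 genes of the F test (highest other 3) and 1 the 7 of Luciferase (highest other 2). The real split thus stood alone in these 4 counts. The other splits do not repeat the batch adjustment made before deposit, and the F test counts can hold the targeted genes. Chance is therefore not excluded for the genes other than the targets. The mean correlation of 0.518 was reached by 27 of the splits (highest other 0.552), so chance cannot be excluded for it either.

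Signal over background was not tested, since the centred values hold no level. Genes near the floor limit what a fold means, and 1015 genes had a probe set below −4 on some array.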

Other observations

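The tests of this part, the lists between knockdowns, the covariance with each group as reference and the groups against the rest, were chosen after the result was seen. Cholesterol and fatty acid synthesis genes were called as a list in 4 of the 6 comparisons between knockdowns, and no list was with an estimated correlation. They were higher in the PARG than in the macroH2A lines (median 0.19, camera adjusted p = 1.2e-07, and adjusted p = 0.400 with an estimated correlation) and higher in the SIRT1 than in the macroH2A lines (0.13, adjusted p = 4.3e-04, and 0.916 with an estimated correlation). They were lower in the PARP-1 than in the PARG lines (−0.13, adjusted p = 7.9e-05, and 0.904 with an estimated correlation) and than in the SIRT1 lines (−0.09, adjusted p = 0.0379, and 0.920 with an estimated correlation). Cytosolic ribosomal protein genes were lower in the PARP-1 lines than in the PARG (−0.07, adjusted p = 0.00254), macroH2A (−0.10, adjusted p = 9.6e-05) and SIRT1 lines (−0.11, adjusted p = 9.4e-06), with adjusted p values of 0.904, 0.829 and 0.676 with an estimated correlation.

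M phase genes were higher in the PARP-1 than in the PARG lines (0.12, adjusted p = 7.0e-04, and 0.904 with an estimated correlation) and lower in the PARG than in the macroH2A lines (−0.19, adjusted p = 4.8e-06, and 0.850 with an estimated correlation). DNA replication genes were higher in the PARP-1 lines than in the PARG lines (0.14, adjusted p = 7.9e-05, and 0.904 with an estimated correlation) and the SIRT1 lines (0.08, adjusted p = 0.00533, and 0.912 with an estimated correlation). Estrogen receptor targets were higher in the PARP-1 than in the SIRT1 lines (0.16, adjusted p = 0.00533, and 0.676 with an estimated correlation), as were interferon stimulated genes (0.19, adjusted p = 0.0379, and 0.371 with an estimated correlation). Genes of the unfolded protein response were lower than in the macroH2A lines in the PARG lines (−0.12, adjusted p = 0.00206, and 0.801 with an estimated correlation) and the SIRT1 lines (−0.12, adjusted p = 4.5e-05, and 0.916 with an estimated correlation), and higher in the PARP-1 than in the SIRT1 lines (0.05, adjusted p = 0.0379, and 0.912 with an estimated correlation).

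TNKS2, a tankyrase of the PARP family, was above Luciferase in all 4 knockdowns without passing over all genes, with changes of 0.39 in the PARP-1, 0.44 in the PARG, 0.35 in the SIRT1 and 0.41 in the macroH2A lines (SE 0.10, limma adjusted p = 0.151, 0.101, 0.199 and 0.121). FHL2 in the PARP-1 lines (0.87, adjusted p = 0.0804) and KCNK5 in the PARG lines (0.94, adjusted p = 0.0507), both on the list of estrogen receptor targets, did not pass. Of the 37 genes of that list, 0 passed over all genes in either knockdown, and adjusted over the list alone 1 rose in the PARP-1 lines and 1 rose and 3 fell in the PARG lines.

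Any group used as the common reference gives effects that covary. The mean covariance minus the error of the reference was 0.0719 with Luciferase, 0.0521 with PARP-1, 0.0479 with PARG, 0.0631 with SIRT1 and 0.0525 with macroH2A over all genes, and 0.0311, 0.0221, 0.0217, 0.0193 and 0.0249 over the 8972 genes left without the noisiest 25%. Against the mean of the other groups 79 genes were called for Luciferase (26 higher and 53 lower), 16 for PARP-1, 20 for PARG, 14 for SIRT1 and 9 for macroH2A. Without 1 Luciferase array the count for Luciferase was 43, 44 and 22 for replicates 1, 2 and 3. The first 3 principal components held 10.2%, 9.46% and 8.99% of the variance, of which group membership took 57.6%, 80.6% and 85.1%. Single arrays carried much of this, with PARG replicate 1 at 85.6 on component 1 against 13.5 and 13.2 for the other PARG arrays, macroH2A replicate 2 at 64.5 on component 2 against 18.1 and 18.4, and SIRT1 replicate 1 at 66.4 on component 3 against 39.3 and 26.0.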
